A study of Arabidopsis thaliana with 18 samples.

How the data were processed

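The values used here are the intensities that the authors deposited, 1 per probe set and array, on a linear scale, for 18 Affymetrix ATH1 arrays of Arabidopsis thaliana rosette leaves. The submitters' processing notes name RMA, without a version, as the method that made them. The values themselves had the median of each array's listed values, array controls included, at 200, and part of the table was blank. No value was rescaled here for the main results. Each listed intensity was converted to log2, and blanks were left as missing, not as zero. All columns of values were used (0 were left out).

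The table held 22810 probe sets. Of these, 64 array controls were left out, which left 22746. Blanks made up 31.5% of the values (27.9% to 35.7% per array). A value was given on all arrays for 13433 probe sets, whose median level was 245, on some arrays for 4906, whose median level was 39.3, and on none for 4407. The annotation given named 1 gene for 13513 probe sets and several for 503, and it held no entry for 8730. Results for the last group are counted and not named. Where a gene on a list had more than 1 probe set, the one with the highest mean was used.

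The design written before the values were seen took them to be log2 values and planned no filter. After the blanks were seen, a probe set was tested in a comparison only where each of its groups had at least 2 listed values. With blanks for low values, a change from or to an undetected level has no log2 value, so probe sets listed on all 3 arrays of a group and on none of the other were counted separately. That count was compared with the other ways to divide the same 6 arrays 3 against 3, which are 10 with the real one.

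A linear model with the means of the 6 groups was fitted per probe set to all 18 arrays in limma (lmFit and eBayes), and 7 contrasts were read from it: the safener response in each of 3 genotypes, the difference of that response between each mutant and wild type, and each mock treated mutant against mock treated wild type. The differences of the responses share their arrays with the responses and with the mock comparisons, and all comparisons that involve wild type share the wild type arrays. Adjusted p values are those of limma with Benjamini-Hochberg adjustment over the probe sets tested in a comparison, and a probe set was called at an adjusted p under 0.05. Errors in the text are SE for log2 changes and SD for intensities. The number of arrays, 3 per group, limits the precision. Replicate numbers were not used as pairs.

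The gene lists, 27 in all, were fixed before the data were examined, and 8 more were added after results had been seen. Of the lists fixed before, the targeted genes, the other TGA factors with ICS2, the ABC transporter family and the senescence, flower and xylem lists had 0 members named in the annotation given, so they were not analysed here. The genes that the mutants lack could for that reason not be used to check the sample labels. The list of SCL14 and TGA dependent xenobiotic response genes was written from general knowledge of earlier work, and whether any member came from a study of these arrays was not established. For each list the members that changed were counted both with the adjustment over all probe sets tested and with one over the list alone, and a count given once was the same both ways.

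Lists with at least 3 measured members were tested with fry and camera. The p value of fry tests whether the genes of a list move on balance one way, and its mixed p value tests whether they change in either direction. Neither compares a list with other genes, which camera does. Both use only members with values on all arrays. Camera was run with its preset correlation of 0.01 and again with an estimated correlation. List p values were adjusted with Benjamini-Hochberg over the lists tested in a comparison.

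The size of the safener response was compared between a mutant and wild type on probe sets that had risen at least 2-fold at an adjusted p under 0.05 in the genotype that takes no part in that comparison. Only those with values on every array of the mutant and wild type were used. The median difference was tested with an exact two-sided permutation test that exchanges genotype labels within each treatment (400 relabellings, smallest p 0.005). A division of 3 arrays against 3 allows no p under 0.1, so the divisions are given as counts.

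Genes are named by a rule. Among probe sets of 1 gene, each safener response gives the 10 most raised and the 6 most lowered called genes whose 3 treated arrays all lay beyond the 3 mock arrays. The differences of the responses and the mock comparisons give up to 6 genes with the largest changes in each direction. Each list gives up to 4 members with the smallest adjusted p. Chance alone puts 3 arrays wholly beyond 3 others in 10% of the divisions.

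The fit and the list tests were tested on simulated data with 200 changed probe sets. For the wild type safener response (14432 probe sets), 49.3% of the simulated changes of log2 0.5 were recovered, 94.0% of those of log2 1 and 100% of those of log2 2. For the difference of the response between tga2tga3tga5tga6 and wild type the shares were 7.46%, 80.6% and 98.5%. With no simulated change there were 0 calls by limma with Benjamini-Hochberg adjustment. False calls numbered 12 of 174 and 3 of 127. All 20 changed lists were found by each list test, and of the unchanged lists among the 100 fry called 1 and camera 0 with either correlation. The simulated noise was independent between probe sets and the lists were drawn at random. These counts therefore do not cover lists of genes that vary together. Every member of a changed list was moved up by log2 0.5, so lists with members that move both ways are not covered either. The real wild type response had 4738 of 14704 probe sets called, far more than the 200 changed here. The shares recovered may therefore differ in the real comparison. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.

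The results were also computed with the replicate number as a block, a fit of only the arrays of a comparison, eBayes with an intensity trend or with robust estimation, a mean log2 value of at least 6, quantile normalization, centring on each array's median, only probe sets that name 1 gene, array weights, and leaving out each array in turn. For the size of the response, no fold minimum, the 100 raised genes with the smallest p and the mean in place of the median were used too. Chosen after the data were seen were centring on the probe sets listed on all arrays, only those probe sets, leaving out a pair of arrays that deviate together, and taking genotype means off before relabelling.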

Results

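Transcript levels were measured on 18 Affymetrix ATH1 arrays, hybridized with RNA from the rosettes of soil-grown Arabidopsis thaliana at an age of 4 weeks. Safeners are compounds that protect crops from herbicide injury, and the spray combined mefenpyr (5 mM) with isoxadifen (7.2 mM), while the mock spray held the solvent in place of the safeners. The safeners were given in a formulation with an emulsifier, and whether the mock spray held it too was not given in the sources used here, so the safener responses compare the formulation as sprayed with mock. The 3 genotypes were wild type Col0, tga2tga3tga5tga6, which lacks several TGA transcription factors, and sid2-2, which lacks the isochorismate synthase that makes most stress-induced salicylic acid. The labels give 3 biological samples for each genotype and treatment. The time between spray and harvest and the ecotype of the mutants were not given in the sources used here. Each array had between 14627 and 16408 probe sets with an intensity, of 22746, and arrays of the same group correlated at r = 0.977 to 0.994 across probe sets, which are not independent replicates. The genes disrupted in the mutants were not analysed here, since the annotation given did not name them.

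The first question was which genes the safener spray changes in wild type leaves. The largest increase was that of AT1G30700, a berberine bridge enzyme-like oxidase, which rose from an intensity of 37.2 ± 8.19 with mock to 521 ± 59.9 with safener (mean ± SD, n = 3), 14.2-fold (log2 3.82, SE 0.20, limma adjusted p = 6.31e-10, Benjamini-Hochberg). The small heat shock protein gene AT2G29500 rose 10.2-fold, from 62.9 ± 4.37 to 646 ± 79.6 (log2 3.36, SE 0.24). AT2G32190 rose from 47.6 ± 8.2 to 534 ± 166, and AT1G56060 from 175 ± 24.7 to 1307 ± 491. Both of these genes were also among those that set replicate 1 of this safener group apart from its group. The glucosyltransferase IAGLU (AT4G15550), which acts on indole-3-acetic acid, rose from 94.7 ± 10.46 to 535 ± 144 (log2 2.46, 5.51-fold), and the beta-glucosidase BGLU45 (AT1G61810) from 30.1 ± 3.82 to 169 ± 37.6. Further increases were those of the peroxidase AT4G33420 (log2 2.82), the receptor-like kinase B120 (AT4G21390, log2 2.59), AT4G39670 (log2 2.52) and AT1G19020 (log2 2.39). Decreases were smaller. AT4G17470 fell from 347 ± 106 to 96.7 ± 12.8 (log2 -1.81, SE 0.24, 3.50-fold, limma adjusted p = 1.75e-05). The tubulin gene TUB1 (AT1G75780) fell from 141 ± 21.8 to 52.9 ± 22, the lipid transfer protein family gene AT5G05960 from 223 ± 37 to 68.7 ± 18.8, and the triterpene synthase LUP5 (AT1G66960) from 196 ± 29.1 to 68.5 ± 3.13. The thaumatin-like gene ATLP-1 (AT1G18250, log2 -1.37) and the aspartyl protease AT5G07030 (log2 -1.41) fell as well.

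Among detoxification genes, 7 of the 8 measured members of the list of SCL14 and TGA dependent xenobiotic response rose and 0 fell, also when adjusted over the list alone (7 and 0), with a median log2 change of 1.17. The glucosyltransferase UGT73B5 (AT2G15480) rose from 99.9 ± 9.84 to 386 ± 99.3, AT4G01870 from 1517 ± 217 to 3923 ± 739, AT3G04000 from 170.4 ± 6.01 to 411 ± 15.8, and the alkenal reductase AER (AT5G16970) from 286 ± 29.9 to 598 ± 32.6. This list moved up by fry (limma adjusted p = 7e-06) and against other genes by camera (adjusted p = 0.000422, and adjusted p = 0.115 with an estimated correlation). Of 8 tau glutathione transferases, GSTU25 (AT1G17180) rose (log2 1.35, from 165 ± 48.8 to 416 ± 98.6) and GSTU20 (AT1G78370) fell (log2 -0.54), and adjusted over the list alone 2 rose and 3 fell. The median (0.07) and the mean (0.12) of that list were above zero, while fry, which used the 4 members with values on all arrays, gave a downward move (adjusted p = 0.0185, and 0.403 by camera). With only probe sets of a mean log2 value of at least 6 the list median was -0.24. The 1 measured phi member, GSTF4 (AT1G02950), rose (log2 0.64). In the UGT family 7 of 30 members rose and 4 fell, and the same numbers were found when adjusted over the list alone. UGT76B1 (AT3G11340), a glucosyltransferase of salicylic acid and isoleucic acid, rose from 603 ± 34.3 to 1495 ± 34.3. In the cytochrome P450 family 3 of 12 rose and 3 fell (4 and 4 adjusted over the list alone), with CYP71B22 (AT3G26200) raised from 130 ± 9.43 to 334 ± 29.5 and CYP78A9 (AT3G61880) lowered (log2 -0.98). By the mixed test of fry, which counts change in either direction, members of these families changed (adjusted p = 2.24e-11 for the UGT family and 3.08e-10 for the P450 family). That test does not compare a list with other genes. Over all probe sets 2190 of 14704 were higher and 2548 lower, so these p values do not set the 2 families apart from other genes.

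Stress and hormone genes made up a further group. All 3 measured members of the heat shock list rose, of which AT5G37670 (log2 0.61) was not called without safener replicate 3 (adjusted p = 0.0536, the highest over its alternatives), with AT5G48570 from 79.2 ± 3.98 to 219 ± 20.8 and AT5G51440 from 316 ± 75.9 to 788 ± 63.4 (list median log2 1.35, fry adjusted p = 1.45e-05, camera adjusted p = 0.00268, adjusted p = 0.115 with an estimated correlation). The glutaredoxin GRX480 (AT1G28480), a gene known to respond to salicylic acid, rose from 231 ± 29.1 to 378 ± 23.2, and SAG101 (AT5G14930) gave log2 -0.11. The 2 plant defensins of the jasmonate list rose, PDF1.2 (AT5G44420) from 254 ± 25.6 to 556 ± 275 and PDF1.2b (AT2G26020) from 326 ± 68.9 to 527 ± 102, but neither was called without replicate 1 of the safener group, nor PDF1.2b without mock replicate 2 (adjusted p of up to 0.0742 for PDF1.2 and 0.0883 for PDF1.2b over the alternatives). The PDF1.2b probe set carries the suffix _x_at, which on these arrays marks probes that may also bind other transcripts. The 2 defensins may therefore not be separate measurements, here and in the comparisons below. In the WRKY list WRKY6 (AT1G62300) rose from 196 ± 38.6 to 633 ± 32.8 and WRKY22 (AT4G01250) rose (log2 1.19), while WRKY47 (AT4G01720) fell (log2 -0.87). The list's median was -0.05, its mean 0.29 and its test upward (fry adjusted p = 0.0185). The mitochondrial stress gene NDB2 (AT4G05020) rose (log2 0.78), as did the glutathione reductase GR1 (AT3G24170, log2 0.55), and the sulfite reductase SIR (AT5G04590) fell (log2 -0.74). Of the glucosinolate and flavonoid lists 1 of 2 members fell, of the photosynthesis list 1 of 5, and of the drought and cell cycle lists the 1 measured. These lowered members were the cold-regulated gene COR15A (AT2G42540, log2 -1.14), the aminotransferase BCAT4 (AT3G19710, log2 -0.71) of glucosinolate synthesis, dihydroflavonol reductase DFR (AT5G42800, log2 -1.72), the antenna protein gene LHCB4.2 (AT3G08940, log2 -0.73) and the mitotic kinase AUR1 (AT4G32830, log2 -0.61). The root marker PYK10 (AT3G09260, log2 -0.29), the guard cell marker FMA (AT3G24140, log2 -0.07) and the endoplasmic reticulum gene CRT1b (AT1G09210, log2 0.25) were not called, although CRT1b was when adjusted over the list alone, as were 1 further lowered member of the sulfate list and 1 of the flavonoid list. The sugar transporter SWEET11 (AT3G48740) of the phloem list fell (log2 -0.35) but was not called without replicate 3 of the safener group (adjusted p = 0.0664, the highest over its alternatives). With safener SWEET11 also went from 2172 ± 73.8 to 1418 ± 151 in tga2tga3tga5tga6 and from 2149 ± 97.1 to 1370 ± 167 in sid2-2. Of the housekeeping controls PEX4 (AT5G25760) gave log2 0.06, and 1 of 3 was called, AT4G34270, at log2 -0.30 (adjusted p = 0.02, and up to 0.0828 over the alternatives, with the call lost without mock or safener replicate 2 or 3).

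In wild type 2190 of 14704 probe sets were higher and 2548 lower (limma, Benjamini-Hochberg), of which 440 and 111 by at least 2-fold, and 2457 of the called ones named 1 gene. A further 90 probe sets had values on all safener arrays and no mock array, and 64 the reverse, against at most 45 for both together in the highest other division of the arrays. Array weights gave 3295 higher and 4295 lower. Leaving out 1 array gave 1765 to 2113 higher and 1700 to 2901 lower.

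**Figure D1:**
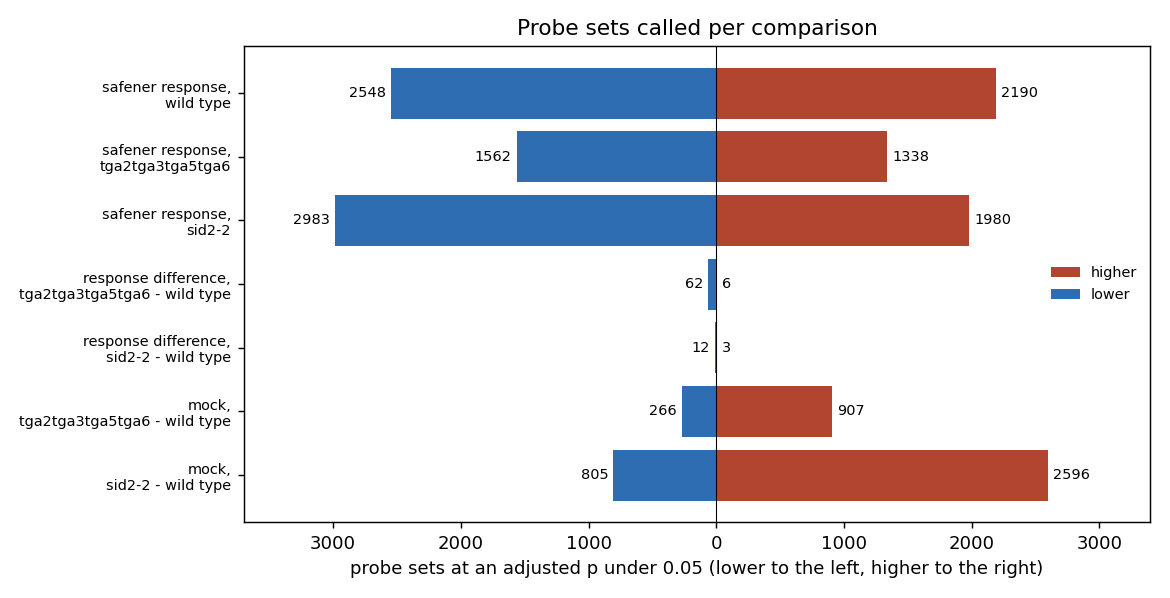
Probe sets at an adjusted p under 0.05 in each of the 7 comparisons, lower to the left and higher to the right (horizontal axis, number of probe sets). The safener responses in wild type, tga2tga3tga5tga6 and sid2-2 held 4738, 2900 and 4963 called probe sets, and the differences of the responses 68 and 15.

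**Figure D2:**
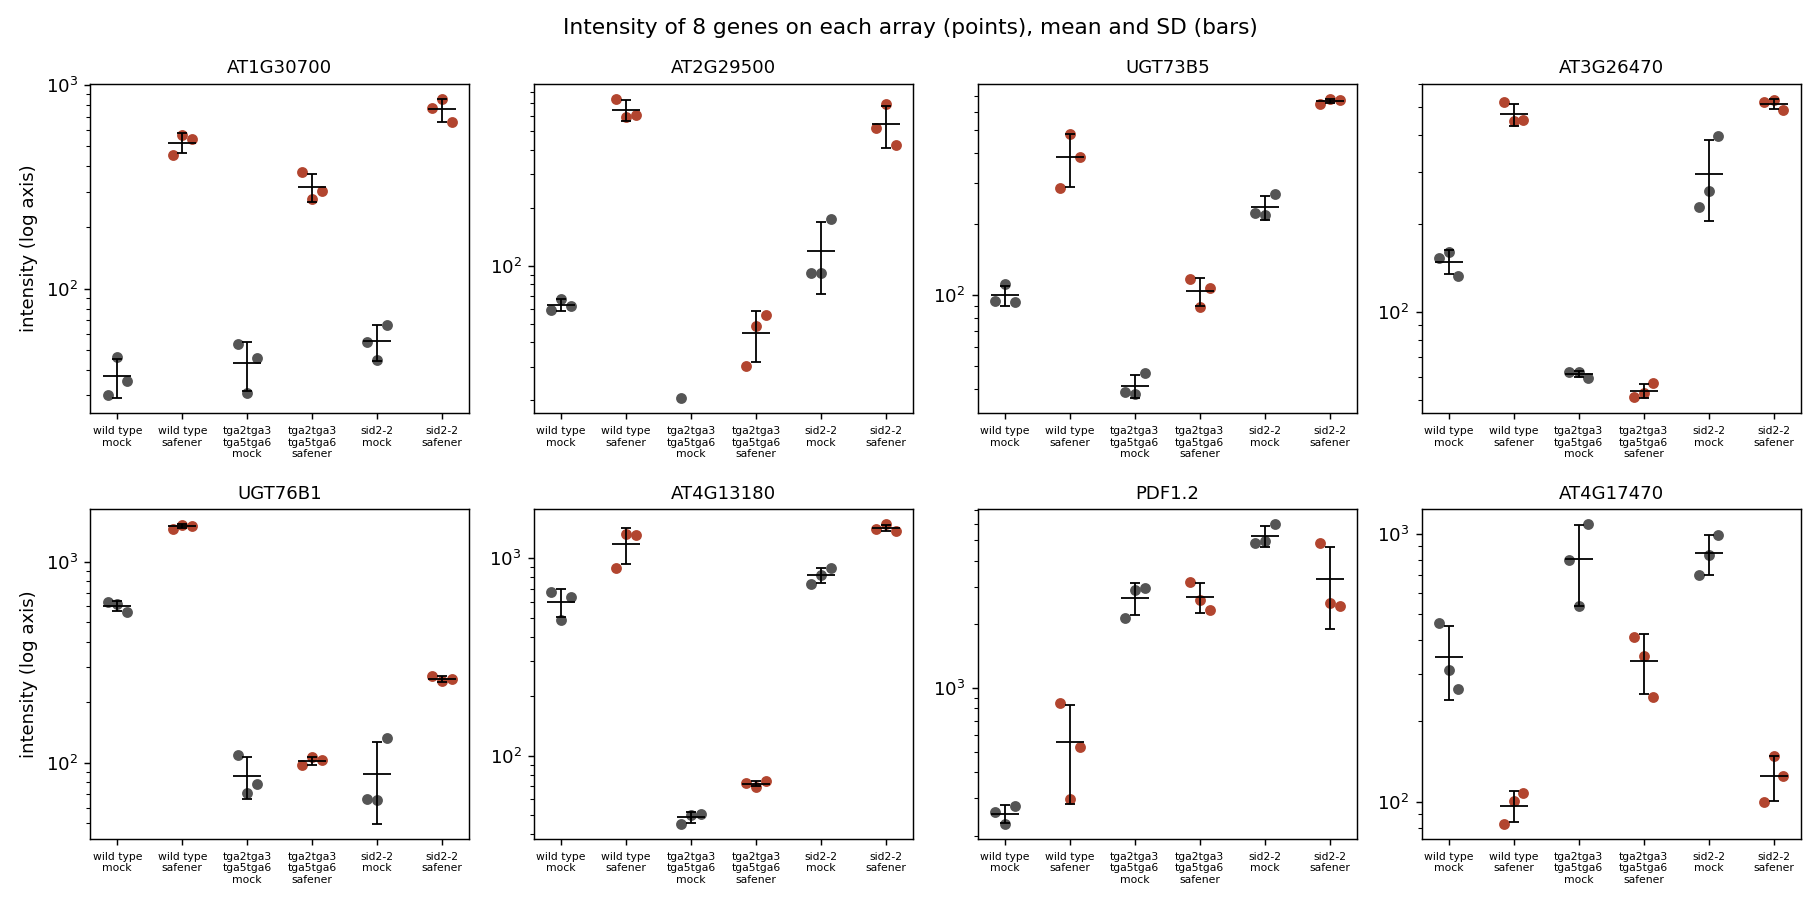
Intensity (vertical log axis) of 8 genes in each of the 6 groups, with 1 point per array, the mean as a horizontal line and the SD as an error bar. With safener AT2G29500 was lower in tga2tga3tga5tga6 (44.9 ± 13.3) than in wild type. It had a value on only 1 mock array of that mutant (20.5), so its response there was not tested. PDF1.2 was high in both mock treated mutants (2674 ± 462 and 5260.1 ± 606).

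The next comparison asked which genes the safeners change in plants without the TGA factors. AT1G30700 rose again, from 43.4 ± 11.7 to 317 ± 50.1 (log2 2.90, SE 0.20, 7.45-fold, limma adjusted p = 3.46e-08). The largest increase was that of AT4G37290, from 72.4 ± 15.8 to 607 ± 56.3 (log2 3.09, SE 0.27, 8.49-fold). AT4G39670 rose from 330 ± 42.9 to 1612 ± 220 and BGLU45 from 51.9 ± 20.3 to 185 ± 23.56. AT1G26380, which like AT1G30700 is a berberine bridge enzyme-like oxidase, rose from 444 ± 96.8 to 1784 ± 133. AT2G16900 rose from 316 ± 39 to 1225 ± 151, AT2G23270 from 167 ± 34.8 to 616 ± 104, AT2G35730 from 18.3 ± 2.33 to 82.4 ± 14.4 and the peroxidase Prx37 (AT4G08770) from 114 ± 25.2 to 407 ± 41.7. The lipid transfer protein family gene AT4G12500 fell from 256 ± 94.6 to 92.2 ± 24.5 (log2 -1.43, SE 0.25, limma adjusted p = 0.000619). DFR fell from 240.4 ± 27.3 to 102 ± 54, the endoglucanase family gene GH9B8 (AT2G32990) from 142 ± 15.5 to 61.7 ± 3.74, and AT1G10640 from 159 ± 11.5 to 70.1 ± 16.5. The wax ester synthase WSD1 (AT5G37300) fell as well (log2 -1.22).

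Of 6 measured members of the SCL14 and TGA dependent list in this mutant 2 rose and 1 fell, also when adjusted over the list alone (2 and 1). AT4G01870 rose from 465 ± 97.4 to 1537 ± 223 and UGT73B5 from 41.1 ± 4.69 to 104 ± 14.1. AT3G04000 gave 138 ± 15.1 and 167 ± 5.03 (log2 0.28). UGT73C1 (AT2G36750) was lower (log2 -0.45) but not called without mock replicate 2 or 3 or safener replicate 1 or 3 (adjusted p of up to 0.107). The list median was 0.16 and its mean 0.46 (fry adjusted p = 0.00689, camera adjusted p = 0.154). The members measured were not the same as in wild type. AER, which rose there, had a value on only 1 safener array of the mutant and was not tested. In the heat shock list 2 of 3 members rose (median log2 0.71), in the UGT family 5 of 33 rose and 4 fell, in the P450 family 2 of 12 rose and 2 fell, and in the WRKY list 2 of 6 rose and 1 fell (3 and 2 adjusted over the list alone). The P450 median (-0.11) and mean (-0.01) were below zero while its test pointed up. WRKY6 (log2 1.53), CYP71B22 (log2 1.01) and NDB2 (log2 0.57) rose as in wild type. Of 7 tau glutathione transferases 0 rose and 2 fell (median log2 -0.25, fry adjusted p = 0.00491, camera adjusted p = 0.215). Of the flavonoid list 0 rose and 2 of 3 fell, or 3 when adjusted over the list alone, which also called 1 lower member each of the cell cycle and housekeeping lists. By limma 0 members of the jasmonate, salicylic acid, photosynthesis and phi transferase lists were called, and GRX480 gave log2 -0.11 and COR15A log2 -0.06.

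In tga2tga3tga5tga6 1338 of 15195 probe sets were higher and 1562 lower with safener (limma, Benjamini-Hochberg), of which 248 and 27 by at least 2-fold. The number of lower probe sets was 703, 904, 760 and 666 without mock replicate 2, mock replicate 3, safener replicate 1 and safener replicate 3, and the number of higher ones was 865 without mock replicate 2. With only the arrays of this comparison in the fit 2473 were lower, and array weights gave 2010 higher and 3056 lower. On all safener arrays and no mock array were 49 probe sets, and 82 the reverse (43 for both together in the highest other division).

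The response of sid2-2 showed which changes occur in plants that make little salicylic acid. AT1G30700 rose from 55.3 ± 10.9 to 759 ± 98.1 (log2 3.79, SE 0.20, 13.8-fold, limma adjusted p = 7.24e-10), AT4G37290 from 130.1 ± 73.2 to 846 ± 20.1 and AT4G39670 from 330 ± 134 to 2197 ± 155. The co-chaperone Hop3 (AT4G12400) rose from 18.8 ± 0.746 to 109.7 ± 14, AT5G44990 from 68.2 ± 15.3 to 373 ± 46.8, AT1G63530 from 36.1 ± 9.18 to 221 ± 24.1 and AT2G29500 from 120 ± 48.5 to 544 ± 134. AT5G59490 rose from 32.4 ± 20.1 to 188 ± 21, and it was among the genes that set mock replicate 3 of sid2-2 apart. AT4G17470 fell from 844 ± 145 to 124 ± 23.9 (log2 -2.77, SE 0.25, 6.81-fold, limma adjusted p = 2.08e-07). AT1G54020 fell from 144 ± 25 to 32 ± 9.37, the jacalin-related lectin JAL23 (AT2G39330) from 408 ± 88.1 to 100.3 ± 26.8, the thionin THI2.1 (AT1G72260) from 244 ± 56.2 to 67.7 ± 11.5 and the endoglucanase family gene GH9B13 (AT4G02290) from 242 ± 35.9 to 82.8 ± 17.1. AT5G05960 fell by a log2 change close to that in wild type (-1.95).

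Of the SCL14 and TGA dependent list 8 of 9 members rose and 0 fell, also when adjusted over the list alone (8 and 0; median log2 1.00, fry adjusted p = 4.16e-05, camera adjusted p = 0.00143, adjusted p = 0.162 with an estimated correlation). UGT73B5 rose from 236 ± 27.2 to 667 ± 15.8, and AT4G01870 (log2 1.49), AT3G04000 (log2 1.00) and UGT73B4 (AT2G15490, log2 1.19) rose too. All 3 measured heat shock members rose, led by AT5G48570 (log2 1.87, list fry adjusted p = 4.16e-05, camera adjusted p = 0.00972, adjusted p = 0.162 with an estimated correlation). In the UGT family 11 of 33 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.0468, adjusted p = 0.636 with an estimated correlation). WRKY22 rose from 46.1 ± 5.17 to 191 ± 2.84 and WRKY6 rose (log2 1.26), while WRKY47 fell (log2 -1.18), so that the WRKY list had a median of -0.19 and a mean of 0.23. GRX480 rose from 94.2 ± 25.7 to 207 ± 14.2. In the jasmonate list 0 rose and 3 of 4 fell, or 4 when adjusted over the list alone, and in the sulfate list 1 of 5 fell, or 3. The jasmonate list had a median log2 change of -0.72 (fry adjusted p = 0.0141, camera adjusted p = 0.238). Of 9 tau glutathione transferases 2 rose and 2 fell (median log2 -0.19, fry adjusted p = 0.000549 downward), with GSTU20 at log2 -0.83. BCAT4 (log2 -1.20), DFR (log2 -1.94) and COR15A (log2 -1.18) fell, and NDB2 rose (log2 0.99). The root marker PYK10 fell from 507 ± 107 to 275 ± 46.9.

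In sid2-2 1980 of 15222 probe sets were higher and 2983 lower (limma, Benjamini-Hochberg), of which 418 and 148 by at least 2-fold. Without safener replicate 3 the number of lower ones was 1970, with only the arrays of this comparison in the fit it was 1873, and with array weights it was 4623. The number of probe sets with values on all safener arrays and no mock array was 65, with 75 the reverse, against at most 87 for both together in the highest other division.

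Whether the TGA factors are needed for the safener response was addressed by the difference of the response between tga2tga3tga5tga6 and wild type, which shares its arrays with the responses above. The gene with the smallest adjusted p among those named was AT3G26470, with a domain of the RPW8 type known from disease resistance, which went from 149 ± 14.2 to 472 ± 40.5 in wild type and from 61.5 ± 1.62 to 53.8 ± 3.07 in the mutant (difference of log2 -1.86, SE 0.21, limma adjusted p = 0.000232, Benjamini-Hochberg). The Kunitz trypsin inhibitor family gene AT1G17860 reached 886 ± 197 with safener in wild type and 163 ± 19.7 in the mutant (difference of log2 -2.0, SE 0.34). The peroxidase AT4G33420 reached 261 ± 51.5 and 32.1 ± 4.17 (-1.96, SE 0.30), IAGLU 535 ± 144 and 82.9 ± 13.9 (-1.49, SE 0.23), AT1G09500 270.3 ± 39.7 and 70.1 ± 8.04 (-1.59), and AT3G25290 129 ± 26 and 79.5 ± 8.1 (-1.51). AT2G29500 had a value on only 1 mock array of the mutant, so its difference was not tested. In the other direction AT1G50590 rose in the mutant (log2 1.55) and gave log2 -0.20 in wild type (difference of log2 1.75, SE 0.34, adjusted p = 0.0244). LUP5 fell in wild type (log2 -1.51) and gave log2 -0.41 in the mutant, a weaker decrease (difference of log2 1.09, SE 0.20, adjusted p = 0.0201). Without mock replicate 1 of the mutant the adjusted p of AT1G50590 was 0.0605 and that of LUP5 0.0656, and over the alternatives the highest were 0.0695 and 0.0656. AT1G50590 also lost its call without any 1 mock array of wild type, safener replicate 2 or 3 of wild type or mock replicate 2 of the mutant, and LUP5 without mock replicate 2 or safener replicate 3 of wild type or mock replicate 3 of the mutant.

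Of 6 members of the SCL14 and TGA dependent list 0 had a higher and 3 a lower response in the mutant, or 4 lower when adjusted over the list alone. AER was not among these members, since it had a value on only 1 safener array of the mutant. UGT73C1 differed by log2 -1.04 (adjusted p = 0.0142, and 0.0530 without mock replicate 3 of the mutant), AT3G04000 by -0.99 (adjusted p = 0.046, and up to 0.154 over the alternatives) and AT5G61820 by -0.74 (adjusted p = 0.0321, and up to 0.120). The levels of UGT73C1 were low, from 39.3 ± 7.18 to 58.7 ± 3.23 in wild type and from 39.8 ± 2.39 to 29.2 ± 1.86 in the mutant. Probe sets listed on only some arrays had a median level of 39.3. AT3G04000 lost its call without any 1 of the arrays but mock replicate 2 of the mutant, and AT5G61820 without any but that array and safener replicate 1 of either genotype. UGT73B5 differed by -0.58 (adjusted p = 0.431). The list median was -0.66 (fry adjusted p = 0.0477, 0.0607 with the replicate number as a block; camera adjusted p = 0.000135, adjusted p = 0.286 with an estimated correlation). The heat shock list had a median of -0.52 with 0 of 3 members called (fry adjusted p = 0.175, camera adjusted p = 0.014, adjusted p = 0.332 with an estimated correlation). In the UGT family 0 of 29 members had a higher and 2 a lower response, or 1 and 4 when adjusted over the list alone. GRX480, which rose in wild type and was not called in the mutant, differed by log2 -0.83 (adjusted p = 0.133, and 0.00238 adjusted over the list alone), and COR15A, lowered in wild type and not called in the mutant, by 1.08 (adjusted p = 0.212, and 0.00269 adjusted over the list alone). The phi transferase GSTF4 was lower (-0.43) only when adjusted over the list alone. In the remaining lists fixed before, 0 members were called by limma either way.

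In total 6 of 14556 probe sets had a higher and 62 a lower response in tga2tga3tga5tga6 than in wild type (limma, Benjamini-Hochberg), with 1158 at an unadjusted p under 0.05. Leaving out 1 array gave 0 to 6 higher, with 0 without mock replicate 2 of wild type, and 27 to 65 lower. The lower count was 38, 37 and 36 without mock replicates 1, 2 and 3 of wild type, 32 without its safener replicate 3, 34 and 27 without mock replicates 1 and 3 of the mutant, and 39, 29 and 36 without its safener replicates 1, 2 and 3. Array weights gave 127 higher and 409 lower, and leaving out wild type safener replicate 1 together with sid2-2 mock replicate 3 gave 10 and 107. The size of the response was measured on 349 of the 418 probe sets that had risen at least 2-fold in sid2-2. The rest had a blank on some array of wild type or the mutant. The median log2 response of the 349 was 1.34 in wild type and 1.03 in the mutant, a median difference of -0.31 (two-sided exact permutation test over 400 relabellings, p = 0.045), and 83.4% responded less in the mutant. With genotype means taken off before relabelling, a form chosen after the data were seen, the exact permutation p was 0.04. The difference stayed between -0.25 and -0.40 when 1 array was left out, but the exact p passed the threshold only without mock replicate 2 or safener replicate 1 of wild type or mock replicate 2 or safener replicate 3 of the mutant. Without any other array it was 0.05 or more, up to 0.105 without mock replicate 1 of the mutant or mock replicate 3 of wild type. It was 0.06 with the arrays centred on probe sets listed throughout. With no fold minimum the difference was -0.16 (exact p = 0.03), and on the 100 raised genes with the smallest p it was -0.52 (exact p = 0.005).

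**Figure D3:**
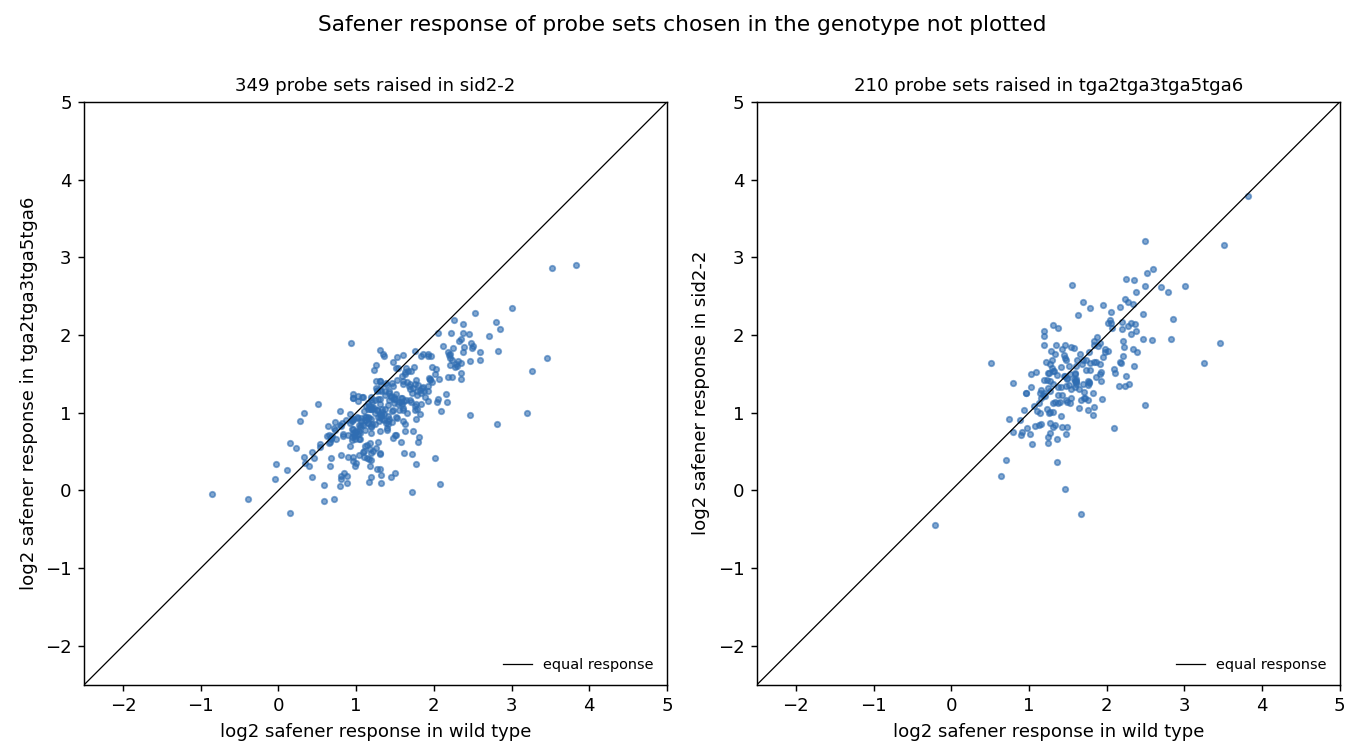
Log2 safener response in wild type (horizontal axis) against that in tga2tga3tga5tga6 (left panel, 349 probe sets chosen in sid2-2) or in sid2-2 (right panel, 210 probe sets chosen in tga2tga3tga5tga6), with 1 point per probe set and a line of equal response. Below the line lie 83.4% of the points in the left panel and 63.3% in the right panel.

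The difference of the response between sid2-2 and wild type addressed the part of salicylic acid synthesis in the safener response. AT3G23550, a MATE efflux family gene, rose from 309 ± 42.2 to 811 ± 113 in wild type, while in sid2-2 it was at 1798 ± 109 with mock and 1685 ± 96.1 with safener (difference of log2 -1.49, SE 0.19, limma adjusted p = 0.00183, Benjamini-Hochberg). AT4G24350 went from 171 ± 6.22 to 249.6 ± 3.49 in wild type and from 865 ± 128 to 429 ± 66.8 in sid2-2 (-1.56, SE 0.20, adjusted p = 0.00183). The glucanase family gene AT4G16260 went from 781 ± 155 to 1637 ± 357 in wild type and from 2789.8 ± 83.4 to 2008 ± 355 in sid2-2 (-1.56, SE 0.23, adjusted p = 0.00638). For Prx37 the difference was -1.97 (SE 0.36, adjusted p = 0.0449), with an adjusted p of 0.122 without safener replicate 3 of sid2-2 and of up to 0.130 over all alternatives. In the jasmonate list PDF1.2 differed by -1.77 (adjusted p = 0.114) and PDF1.2b by -1.38 (adjusted p = 0.0844), and 0 of 3 members were called, or 2 when adjusted over the list alone. The list median was -1.38, the value of PDF1.2b itself (fry adjusted p = 0.028, 0.0706 without the arrays wild type safener replicate 1 and sid2-2 mock replicate 3; camera adjusted p = 0.00126, adjusted p = 0.144 with an estimated correlation). Both tests count PDF1.2 and PDF1.2b as separate members, although their probe sets may not be separate measurements. In the P450 family 0 of 11 were called, or 1 lower, CYP71B22, when adjusted over the list alone (median log2 -0.24, fry adjusted p = 0.102, camera adjusted p = 0.0359, adjusted p = 0.365 with an estimated correlation). The SCL14 and TGA dependent list had a median of -0.29 with 0 of 8 members called by limma, or 1 lower, AER, when adjusted over the list alone. That adjustment also called 1 lower member each in the heat shock, root and phloem lists and 1 higher member each in the UGT and WRKY lists.

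In total 3 of 14524 probe sets had a higher and 12 a lower response in sid2-2 than in wild type (limma, Benjamini-Hochberg), with 1375 at an unadjusted p under 0.05. Array weights gave 77 higher and 135 lower, the replicate number as a block 1 and 5, and only the arrays of this comparison in the fit 1 and 4. Only the 4 lower genes given above had a probe set that names 1 gene. Leaving out 1 array gave 0 to 6 higher, with 6 without safener replicate 2 of wild type, and 5 to 18 lower. The lower count was 5, 6 and 7 without mock replicate 3, safener replicate 1 and safener replicate 3 of wild type, 7 without mock replicate 2 or 3 of sid2-2, and 5 without its safener replicate 2 or 3. The higher count was 0 without any 1 mock array or safener replicate 1 of wild type, mock replicate 2 of sid2-2 or its safener replicates 1 or 2, and 1 without its safener replicate 3. With the arrays centred on probe sets listed throughout 5 were higher and 11 lower (31.3% higher). On 210 of the 248 probe sets chosen in tga2tga3tga5tga6, those without a blank in wild type or sid2-2, the median log2 response was 1.59 in wild type and 1.49 in sid2-2, a median difference of -0.10 (two-sided exact permutation test, p = 0.745) with 63.3% smaller in sid2-2. These probe sets were chosen for rising without the TGA factors, so genes that rise only with those factors were left out. They are also not the probe sets behind the -0.31 of tga2tga3tga5tga6. With genotype means taken off before relabelling, the exact permutation p of the -0.10 was 0.6. Without mock replicate 3 of sid2-2 that difference was 0.0407 (exact p = 0.845).

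The mock treated plants showed what the loss of the TGA factors changes without safener. The short-chain dehydrogenase AT4G13180 was at 600.4 ± 99.4 in wild type and 48.7 ± 3.17 in tga2tga3tga5tga6 (log2 -3.61, SE 0.14, 12.2-fold, limma adjusted p = 1.67e-12, Benjamini-Hochberg). UGT76B1 fell from 603 ± 34.3 to 86.2 ± 20.2, the organic cation transporter OCT5 (AT1G79410) from 212 ± 8.31 to 34.3 ± 3.7 and AT1G19960 from 1124 ± 73.3 to 241 ± 9.99. The expansin-like EXLB1 (AT4G17030), named from a list chosen after the data were seen, fell from 429 ± 96.2 to 42.1 ± 2.9 (n = 2 in the mutant). AT3G28510 fell from 92.4 ± 32.2 to 22.8 ± 5.61 and the pectin methylesterase ATPMEPCRB (AT4G02330) fell as well (log2 -2.08). PDF1.2 was higher in the mutant, at 2674 ± 462 against 254 ± 25.6 (log2 3.39, SE 0.28, 10.46-fold, limma adjusted p = 1.61e-07), and PDF1.2b at 1412 ± 163 against 326 ± 68.9. AT2G20870 was at 310.1 ± 69.5 against 29.3 ± 6.62, AT1G54020 at 282 ± 76.1 against 37.1 ± 3.15, and AT3G28220 (log2 2.03) and JAL23 (log2 1.86) were higher too.

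Of 7 members of the SCL14 and TGA dependent list 0 were higher and 4 lower in the mutant, or 5 when adjusted over the list alone (median log2 -0.89, fry adjusted p = 6.08e-05, camera adjusted p = 1.14e-08 and 0.0158 with an estimated correlation). AER fell from 286 ± 29.9 to 74.4 ± 4.33 (n = 2 in the mutant), AT4G01870 by log2 -1.72, UGT73B5 by -1.28 and AT5G61820 from 1597 ± 99.7 to 862 ± 102. GRX480 fell from 231 ± 29.1 to 66.8 ± 4.45. Adjusted over the list alone, 1 further member was higher in each of the salicylic acid, WRKY, glucosinolate, drought and root lists, and 1 was lower in the heat shock list. Of the jasmonate list 3 of the 4 measured members were higher and 0 lower, or 4 when adjusted over the list alone (median log2 2.33, fry adjusted p = 6.37e-06, camera adjusted p = 1.13e-05 and 0.0158 with an estimated correlation), among them THI2.1, at 50.3 ± 23.9 on 2 wild type arrays and 279 ± 70.1 in the mutant. In the P450 family 3 of 12 were higher and 0 lower (5 and 0 adjusted over the list alone; fry adjusted p = 0.000814, camera adjusted p = 0.00858, adjusted p = 0.226 with an estimated correlation), with CYP71B22 at log2 0.76. In the UGT family 2 of 30 were higher and 5 lower (3 and 8 adjusted over the list alone; camera adjusted p = 0.0141, adjusted p = 0.579 with an estimated correlation). DFR was higher in the mutant (log2 1.43), and 1 of 3 members of the mitochondrial list was higher, or 2 when adjusted over the list alone (fry adjusted p = 0.00709, camera adjusted p = 0.0175, adjusted p = 0.336 with an estimated correlation). A spiked control of the arrays was higher on all 3 mock arrays of this mutant (log2 10.97 to 11.09) than on those of wild type (10.29 to 10.88), which chance gives in 10% of divisions, and mock treated sid2-2 was at 10.58 to 11.10. With the safener arrays included the ranges of this mutant and wild type met at 10.88.

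Against wild type 907 of 15018 probe sets were higher and 266 lower in mock treated tga2tga3tga5tga6 (limma, Benjamini-Hochberg), a share of 77.3% higher. With the arrays centred on probe sets listed throughout, 653 were higher and 435 lower (60.02%). Without mock replicate 2 of wild type the counts were 514 and 148, without its mock replicate 3 598 were higher, without mock replicate 2 of the mutant 157 were lower, without its mock replicate 3 484 were higher, and array weights gave 2217 and 686. On all mutant arrays and no wild type array were 135 probe sets, and 26 the reverse (38 for both together in the highest other division). The mock arrays of the mutant also had values for more probe sets (15774 to 15935) than those of wild type (15211 to 15340).

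The last comparison asked what the loss of salicylic acid synthesis changes in mock treated plants. PDF1.2 was at 5260.1 ± 606 in sid2-2 and 254 ± 25.6 in wild type (log2 4.37, SE 0.28, 20.7-fold, limma adjusted p = 3.33e-09, Benjamini-Hochberg), and PDF1.2b at 2803 ± 1038 against 326 ± 68.9. AT3G23550 was at 1798 ± 109 against 309 ± 42.2, and AT2G43590, of the chitinase family, at 1029 ± 76.5 in sid2-2 (log2 2.44). AT1G09500 (log2 2.45) and AT2G20870 (log2 2.40) were higher too. UGT76B1 was lower, at 88.4 ± 38.8 against 603 ± 34.3 (log2 -2.85, limma adjusted p = 7.29e-09), much as in the other mutant. The legume lectin family gene AT5G03350 fell from 3553 ± 76.4 to 833 ± 63.5, AT5G39520 from 293 ± 14 to 66.2 ± 14.5, AT5G45000 from 107 ± 7.04 to 24.1 ± 4.14, LUP5 from 196 ± 29.1 to 47.3 ± 4.48 and the invertase family gene cwINV6 (AT5G11920) from 234 ± 6.16 to 61.9 ± 16.1.

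Unlike in tga2tga3tga5tga6, 6 of 8 members of the SCL14 and TGA dependent list were higher and 1 was lower in sid2-2, also when adjusted over the list alone (6 and 1; median log2 1.00, fry adjusted p = 1.78e-05, camera adjusted p = 0.0226, adjusted p = 0.329 with an estimated correlation). UGT73C1 rose from 39.3 ± 7.18 to 164 ± 29.6, and AER (log2 1.18), UGT73B5 (log2 1.24) and AT5G61820 (log2 0.81) were higher. All 4 measured jasmonate members were higher (median log2 2.701, fry adjusted p = 1.12e-07, camera adjusted p = 6.77e-05 and 0.0413 with an estimated correlation), with THI2.1 at log2 2.34 and the jasmonate methyltransferase JMT (AT1G19640) at 1.14. The others were PDF1.2 and PDF1.2b, whose probe sets may not be separate measurements, and no lipoxygenase, AOS, VSP or JAZ gene of the list was measured. Both measured members of the salicylic acid list were lower, GRX480 from 231 ± 29.1 to 94.2 ± 25.7 and SAG101 by log2 -0.43, the latter with an adjusted p of up to 0.166 when mock replicate 2 or 3 of wild type or mock replicate 1 of sid2-2 was left out. The list's PR genes were not measured. In the P450 family 7 of 12 were higher and 0 lower, also when adjusted over the list alone (7 and 0; fry adjusted p = 1.49e-05, camera adjusted p = 0.0272, adjusted p = 0.329 with an estimated correlation). In the UGT family 8 of 29 were higher and 4 lower (10 and 5 adjusted over the list alone), of the sulfate list 2 of 4 (3 adjusted over the list alone) and of the mitochondrial list 2 of 3 were higher, and GR1 was higher (log2 0.61). Both measured flavonoid members and the 1 drought member were higher, and 1 photosynthesis member lower, only when adjusted over the list alone. Another photosynthesis member, LHCB4.3 (AT2G40100), went the other way, at 752 ± 128 in sid2-2 against 380 ± 88.2 in wild type. The root marker PYK10 was higher in sid2-2 (log2 0.54, adjusted p = 0.0255), a call lost without mock replicate 1 or 3 of wild type or mock replicate 3 of sid2-2 (adjusted p of up to 0.144 over the alternatives).

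**Figure D4:**
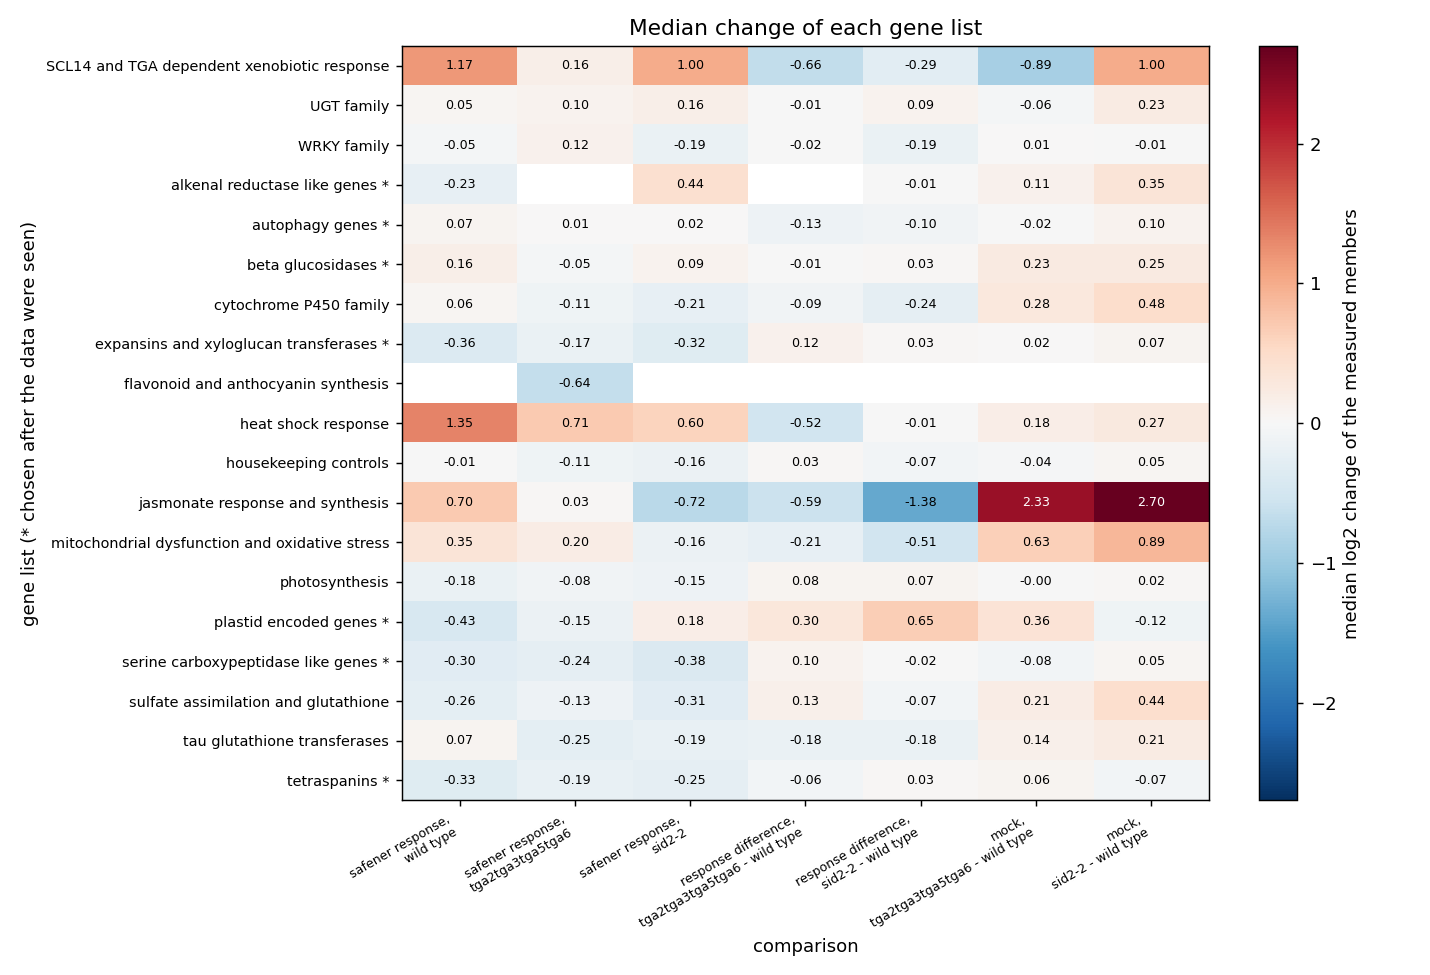
Median log2 change (colour and printed value) of the measured members of each gene list with at least 3 of them (vertical axis) in the 7 comparisons (horizontal axis), with an asterisk for lists chosen after the data were seen. The SCL14 and TGA dependent list was at 1.17, 0.16 and 1.00 in the safener responses, and the jasmonate list at 2.33 and 2.701 in the mock treated mutants. The members measured differ between comparisons, so medians of 1 list are not over the same genes.

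Against wild type 2596 of 15002 probe sets were higher and 805 lower in mock treated sid2-2 (limma, Benjamini-Hochberg), a share of 76.3% higher. With the arrays centred on probe sets listed throughout, 1573 were higher and 1326 lower (54.3%). Without mock replicate 2 of wild type the counts were 1453 and 506, without mock replicate 3 of sid2-2 1664 were higher, with only the arrays of this comparison in the fit the counts were 1483 and 495, and array weights gave 4884 and 1722. On all sid2-2 arrays and no wild type array were 136 probe sets, and 24 the reverse (58 for both together in the highest other division). The mock arrays of sid2-2 also had values for more probe sets (15518 to 16408) than those of wild type (15211 to 15340).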

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

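Of the tests in this part, those of the scaling of the arrays, the relabelling with genotype means taken off first, and the reading of the TGA list's ratio were chosen only after the result was seen.

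Differences of the safener response between a mutant and wild type were singled out because the interaction itself was tested. In tga2tga3tga5tga6 these were the log2 differences of AT1G17860 (-2.0), AT4G33420 (-1.96), AT3G26470 (-1.86), AT1G09500 (-1.59), AT3G25290 (-1.51) and IAGLU (-1.49), and in the other direction those of AT1G50590 (1.75), LUP5 (1.09), AT2G41190 (0.88) and ATPMEPCRB (0.85). AT2G41190 and ATPMEPCRB had adjusted p values of up to 0.126 and 0.121 over their alternatives (limma, Benjamini-Hochberg), for AT2G41190 without mock replicate 3 and for ATPMEPCRB without safener replicate 2 of the mutant. The median of the SCL14 and TGA dependent list (-0.66), the 68 called probe sets and the size of the response (-0.31) were singled out as well. In sid2-2 they were Prx37 (-1.97), AT4G24350 (-1.56), AT4G16260 (-1.56), AT3G23550 (-1.49), the median of the jasmonate list (-1.38) and the 15 called probe sets.

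For the 68 calls in tga2tga3tga5tga6, 7 of 100 drawn relabellings of genotype within treatment gave as many, the real one included, with 760 in the highest other, so that this relabelling did not exclude chance. For the 15 calls in sid2-2 it was 11 of 100, with 4874 in the highest other. Relabellings with several times the real count point to a structure of the samples, since a label exchanged in only 1 treatment carries the difference between genotypes into the interaction. Once each genotype's mean over both treatments was taken off, 1 of 100 relabellings (highest other 1) and 2 of 100 (highest other 21) gave as many. That form was chosen after the result was seen and takes its means from the same arrays under their real labels. It therefore does not exclude chance. For each of the 5 comparisons of 2 groups the arrays divide in only 10 ways, too few for a share under 0.05, and 1 of 10 gave as many calls. The real counts were 4738, 2900 and 4963 for the safener responses in wild type, tga2tga3tga5tga6 and sid2-2, and 1173 and 3401 for the mock treated mutants, with 0, 0, 1, 0 and 0 in the highest other division.

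The smaller safener response in tga2tga3tga5tga6 may come from a lower delivered dose, from a deviating array or from the missing TGA factors. A single common factor on the log2 change of every gene left 25 probe sets called against it, 2 higher and 23 lower, around a median ratio of 0.755 (quartiles 0.611 and 0.914, 378 genes), which argues against that factor as the whole cause. A lower dose need not scale all log2 changes by 1 factor, so the dose stays open. Without wild type safener replicate 1 the median difference was -0.35, so that array was not the cause. Dependence on the TGA factors also stays open. The SCL14 and TGA dependent list lay at percentile 87.4 of random lists in its ratio to the sid2-2 response, past the bound set in advance against the explanation, but only 3 members entered (AT3G04000 0.281, UGT73B5 0.893, AT4G01870 1.17) and they lie on both sides of the median of all genes (0.706), so the value decides nothing.

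Mock treated mutants had more probe sets higher than lower against wild type. Once the arrays were centred on probe sets listed throughout, 54.3% of the calls were higher in sid2-2, against 76.3% before, and 60.02% in tga2tga3tga5tga6, against 77.3%. Such centring takes off a real broad shift as well as one from the scaling of each array to the median of its listed values, so these shares do not speak for scaling, and both stay open. Without mock replicate 3 of sid2-2 the share in that mutant was 68.7%, which lies between the values set for and against that array as the cause. The loss of gene function in the mutants stays open as an untested biological explanation.

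Wild type safener replicate 1 and sid2-2 mock replicate 3 deviated from their groups together (r = 0.563 across probe sets, highest other pair 0.473). Of the 20 genes that set them apart most, 14 were plastid encoded, with psbT, rpoB and atpI higher and rps18, rps19 and rpl16 lower, and without plastid probe sets the correlation was 0.546. After quantile normalization it was 0.5005, which argues against a distortion by intensity that this removes. A swap of both samples was excluded, with 0 of the 2 arrays closer to the other's group (r of 0.981 to its own and 0.929 to the other group, and 0.978 and 0.942). Neither array lay above the rest in the ratio of 3' to 5' signal of the control genes (0 arrays), which argues against degraded RNA, and no biological explanation was tested.

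Outside the main measurement, 1 control probe set on the array had values on the arrays of tga2tga3tga5tga6 alone, at 1238 ± 344 with mock and 1936 ± 253 with safener (mean ± SD, n = 3), and was blank on the 12 other arrays.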

How the results depend on the processing

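The settings that centre on probe sets listed on all arrays, keep only those probe sets, leave out the pair of arrays that deviate together, or take genotype means off were chosen after seeing the data. Each setting changed 1 choice, and the cause of a change was not tested unless stated. Of 552 counts of called probe sets 139 moved by more than 1.5 times. Of 588 list medians 543 kept their call and direction, 24 gained a call, 19 lost it and 2 were reversed. Of 6876 values of named genes 546 lost the call. Of 42 values of the size of the response 31 kept their side of the threshold, 9 lost it and 2 moved.

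The reversed values were both in wild type with a mean log2 value of at least 6, where the median of the tau glutathione transferases was -0.24 and that of the beta glucosidases -0.18. With only probe sets that name 1 gene fewer were tested, and the safener responses had 1098 higher and 1302 lower in wild type, 670 and 832 in tga2tga3tga5tga6, and 976 and 1582 in sid2-2. The differences of the response had 22 lower in tga2tga3tga5tga6 and 0 higher and 4 lower in sid2-2, and the mock treated mutants had 383 and 133, and 1383 and 421. Array weights gave 3295 and 4295 in wild type, 2010 and 3056 in tga2tga3tga5tga6 and 4623 lower in sid2-2. They gave 127 and 409, and 77 and 135, for the differences, and 2217 and 686, and 4884 and 1722, for the mock treated mutants.

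With only the arrays of a comparison in the fit, 2473 probe sets were lower in the response of tga2tga3tga5tga6 and 1873 in that of sid2-2, the difference in sid2-2 had 1 higher and 4 lower, and mock treated sid2-2 had 1483 and 495. For the difference in sid2-2 the replicate number as a block gave 1 and 5, an intensity trend 20 lower, and quantile normalization 1 higher. Centring on probe sets listed throughout gave 5 higher for that difference, 435 lower in mock treated tga2tga3tga5tga6, and 1573 higher and 1326 lower in mock treated sid2-2. Without the pair of deviating arrays the difference had 10 higher and 107 lower in tga2tga3tga5tga6 and 0 and 5 in sid2-2. The size of the response in tga2tga3tga5tga6 was -0.30 (exact permutation p = 0.06) with that centring, and in sid2-2 it was 0.0255 (exact permutation p = 0.95) without the pair. For tga2tga3tga5tga6 it was -0.16 (p = 0.03) with no fold minimum, -0.36 (p = 0.02) after quantile normalization and -0.52 (p = 0.005, the smallest the exact permutation test can give) on the 100 genes with the smallest p.

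Leaving out 1 array gave 1765 to 2113 higher and 1700 to 2901 lower in wild type, 865 to 1232 and 666 to 1368 in tga2tga3tga5tga6, and 1528 to 2193 and 1970 to 2997 in sid2-2. The differences had 0 to 6 and 27 to 65 in tga2tga3tga5tga6, and 0 to 6 and 5 to 18 in sid2-2. The mock treated mutants had 484 to 860 and 148 to 268, and 1453 to 3015 and 506 to 790. The size of the response ranged from -0.40 to -0.25 in tga2tga3tga5tga6 and from -0.17 to 0.0407 in sid2-2. Arrays that moved a count by more than 1.5 times are named beside each comparison, and the higher count of the difference in tga2tga3tga5tga6 was also 1 without wild type mock replicate 1, wild type safener replicate 3 or mutant mock replicate 3, 2 without mutant mock replicate 1, and 3 without mutant safener replicate 1 or 2.

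Replicate numbers did not pair the samples, since pairs of arrays with the same number correlated at r = -0.41 to 0.46 and pairs with different numbers at -0.47 to 0.56. With the replicate number as a block 4674 probe sets were called in wild type, of which 4539 were shared with the 4738. Blanks at low signal over background keep small or undetected transcripts out of the tested probe sets, so these results describe genes with values on at least 2 arrays per group.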

Other observations

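All tests in this part, on added lists, on calls shared between genotypes and on principal components, were chosen only after results were seen.

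Of the expansins and xyloglucan transferases, a list chosen after the data were seen, 0 of 12 members rose and 6 fell in wild type (median log2 -0.36, fry adjusted p = 7e-06, camera adjusted p = 0.0116, adjusted p = 0.115 with an estimated correlation), with EXPA4 (AT2G39700) and EXPA8 (AT2G40610) both at log2 -0.76. In tga2tga3tga5tga6 0 of 11 rose and 4 fell, with XTH16 (AT3G23730) at log2 -0.82, and in sid2-2 1 of 12 rose and 5 fell. Serine carboxypeptidase-like genes had 1 higher and 7 lower of 15 in wild type (camera adjusted p = 0.0397, adjusted p = 0.535 with an estimated correlation), with SCPL45 (AT1G28110) at log2 -0.85 and scpl31 (AT1G11080) at 1.37, and 1 and 8 of 15 in sid2-2. Of the autophagy genes 3 of 11 rose in wild type and 0 fell, led by ATG8H (AT3G06420, log2 1.18). Of the beta glucosidases 3 of 11 rose and 1 fell, with BGLU46 (AT1G61820) at log2 1.27, and the list median was 0.16 (-0.18 with a mean log2 value of at least 6). Of the tetraspanins 1 of 7 rose, TET8 (AT2G23810, log2 0.65), and 3 fell. The alkenal reductase-like genes had 1 of 3 higher, with a median of -0.23 and a mean of 0.17, and the MATE transporter cluster had 0 of 2 called in wild type by limma and 2 of 2 higher in each mock treated mutant.

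Of the plastid encoded genes 0 of 69 rose and 16 fell in wild type with safener (median log2 -0.43, fry adjusted p = 0.0424, and 0.0573 with the replicate number as a block), among them psaA (log2 -1.03), but without wild type safener replicate 1 and sid2-2 mock replicate 3 the median was -0.27 (fry adjusted p = 0.188). The mean log2 level of plastid probe sets was 8.76, 9.58 and 8.97 on wild type safener replicates 1, 2 and 3. It ranged from 9.41 to 9.78 on the wild type mock arrays and from 9.85 to 9.96 on the tga2tga3tga5tga6 mock arrays. In tga2tga3tga5tga6 and sid2-2 0 of 69 were called with safener by limma (medians -0.15 and 0.18).

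The safener responses, which use separate arrays, shared much of their direction. Between wild type and tga2tga3tga5tga6 1121 probe sets were higher in both, where 192 would be shared if the calls were independent, and 1010 lower in both (260.3), with 7 and 2 called in opposite directions. Between wild type and sid2-2 the shared numbers were 1436 higher (285) and 1556 lower (503), and between the mutants 1069 (172) and 1111 (303). The responses correlated at r = 0.836, 0.823 and 0.824 across genes, which are not independent replicates.

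In a principal component analysis the first component (41.7% of the variance) separated treatments, the second (19.5%) sid2-2 from the other genotypes and the third (14.8%) wild type from tga2tga3tga5tga6. On the fourth (6.89%) wild type safener replicate 1 (19.97) and sid2-2 mock replicate 3 (23.602) lay at one end and sid2-2 safener replicate 3 (-17.7) at the other.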
